A study of Homo sapiens with 8 samples.

How the data were processed

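Normal human dermal fibroblasts, primary connective tissue cells of the skin, were plated at 620000 cells per 10 cm plate in medium with serum, per the labels' protocols. On the next day they received 2 µg/ml of a goat antibody that activates the lymphotoxin beta receptor (LTBR), a member of the tumour necrosis factor receptor family. Cells were collected after 0, 2, 6 or 20 h, and libraries were made from polyadenylated RNA. The 8 libraries form 4 groups of 2, by the time point in the labels. Replicates were numbered 1 and 2 within each group by the order of deposition. The libraries numbered 1 carry the library codes 1 to 4 in the labels and those numbered 2 the codes 5 to 8, so the replicate number coincides with the code series that served as a block in an alternative. The labels do not say that a series marks a shared culture or day, so the fit reported here has no block. The labels do not say whether the libraries of a group came from separate cultures or donors, so p-values measure the spread between these libraries, which may be technical.

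The authors deposited, for each library, whole-number counts for 26364 gene symbols. The submitters' processing notes name genome build hg19 and DESeq2. The aligner, the counting program, the annotation and whether strand was used are not given in the sources used here. The deposited tables also hold log2 values for the same genes. They carry the name DESeq2, but the transformation by which the authors made them is not named in the sources used here. These log2 values are exactly 0 for all 6962 genes without a count in any library and for no other gene. Across the tested genes, which are not independent replicates, their differences between time points correlated with the log2 fold changes of the counts at 0.586 to 0.628. For the 7718 genes with more than 500 counts in every library, the deposited values differed little from log2 counts scaled by DESeq2 size factors. The median absolute difference there was 0.021. The deposited log2 values were used only for an alternative test. The reference used here is another build, so no coordinates are given; it served for gene synonyms and for the sequence of transcripts. Of the 494 entries of the gene lists, 5 were found under an older symbol. Reads of close copies, such as CXCL1 and CXCL3, OAS1 and OAS2 or MX1 and MX2, can be split or lost by counting, so levels of such genes are uncertain.

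Counts were tested with edgeR 4.0.16 in R 4.3.3. The filter filterByExpr by time point kept 14289 genes. Libraries were scaled by TMM, and a quasi-likelihood model with robust estimation and 1 mean per time point was fitted to all 8 libraries together, with 4 residual degrees of freedom and a median of 10.2 prior degrees of freedom. The common biological coefficient of variation was 6.54%. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, for 2, 6 and 20 h against 0 h, for the 3 comparisons between stimulated time points, and for any difference among the 4 time points. Genes and list members given as called, higher, lower, rising or falling are those of edgeR unless another tool is named. Standard errors of log2 fold changes were taken from the F statistic. Levels are given in CPM, counts scaled to the effective library size after TMM, as mean ± SD over 2 libraries. Totals of 29738091 to 43201016 counts per library put the level of 3 counts between 0.0694 and 0.101 CPM of the unscaled library total, which covers counting error alone.

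Before the data were examined, 28 gene lists, the tests and the rule for named genes were fixed. Named genes are the 10 with the highest and the 10 with the lowest log2 fold change in each comparison with 0 h, among called genes whose stimulated libraries both lay beyond both 0 h libraries and whose mean reached 5 CPM in the higher group. Up to 4 called members of each list with the largest absolute change were added, and LTBR, NFKB2, RELB, TRAF3 and EWSR1 were always included. Symbols of clones and loci were skipped, as were XIST and genes on the Y chromosome. CSF1, BIRC2, MYC, KLF6, DDX58, IFIH1 and NFKBIE fall outside this rule and were chosen after their values were seen, as were APOL6, XAF1, IRF1, PSAT1 and TRIB3. Lists with at least 3 tested members (27 of 28) were tested with camera from limma 3.58.1 at a preset correlation of 0.01, again with a correlation estimated per list, and with fry, with adjustment over the 27 lists. Some genes belong to more than 1 list, such as BIRC3 in the receptor pathway and apoptosis lists, so list results are not independent.

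The alternatives were DESeq2 size factors or total counts for scaling, no or a stricter low-count filter, DESeq2 1.42.0, limma-voom, a fit of the 4 libraries compared, the library code series as a block, no robust estimation, an adjusted p under 0.01, and leaving out each library. In that last case the lone library of a time point is assumed to vary like the other groups. After the data were seen, 2 were added: limma on the deposited log2 values, and removal of each library's trend with GC content and transcript length. GC content and length came from the longest transcript of each symbol in GENCODE, which gave values for 13461 genes, 94.2% of those tested.

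The calculation was tested on simulated counts for the comparison of 2 h with 0 h, with 200 of the real genes changed. Over the 14148 genes tested there, edgeR recovered 59.7% of genes changed by 0.5 on the log2 scale, 92.5% of those changed by 1 and 98.5% of those changed by 2, and 3 of 170 calls were false. DESeq2 recovered 161 of the 200 changed genes among 14289 genes, with 9 of 170 calls false, and limma-voom 168 among 14141, with 14 of 182 false. With a GC trend put into 1 simulated library, edgeR recovered 151 of 200 changed genes among 14155, with 5 of 156 calls false. After removal of the trend it recovered 161 of the 186 changed genes with a GC value among 13342, with 11 of 172 calls false. The list test called a raised list of 20 genes and 0 of 27 unchanged lists, among 14289 genes. The simulated genes varied independently of each other and the unchanged lists were random, so list calls among correlated genes were not tested. In the real lists the estimated correlation at 20 h ran from -0.121 to 0.626.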

Results

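The transcriptome of human dermal fibroblasts was followed over 20 h of LTBR stimulation, with 2 libraries at each of 0, 2, 6 and 20 h. LTBR binds lymphotoxin and LIGHT and signals through NF-κB, a family of transcription factors of inflammation. Total counts ranged from 29738091 to 43201016 per library. The genes with the most counts were the matrix genes COL1A1 with 2.07% of all counts, FN1 with 1.49% and COL1A2 with 1.36%, followed by the actin gene ACTB with 1.19%. Ribosomal protein genes took 2.58 to 2.87% of counts and the 10 most abundant genes 9.61 to 11.1%. Libraries of the same time point correlated at 0.9932 to 0.9961 over genes in log2 CPM, and every pair differed by more than sampling noise, with chi-square per degree of freedom of 3.63 to 23.5. The 2 h pair differed most, with an SD of 0.321 for its log2 difference over genes against 0.246 to 0.256 for the other pairs. On the first principal component (29.2% of variance) 2 h replicate 1 lay at -25.6 and 2 h replicate 2 at 0.906. The log2 difference between the 2 h libraries correlated with GC content over genes at r = 0.579, where genes are not independent replicates, against -0.116 to 0.259 for the other pairs. Set against the mean of the 6 libraries of the other time points, GC content and transcript length accounted for an R squared of 0.412 in 2 h replicate 1 and of 0.00855 in 2 h replicate 2. By the same measure R squared was 0.155 and 0.0633 in the 20 h libraries, with correlations with GC content of -0.379 and -0.244, and 0.0134 to 0.051 in the 0 and 6 h libraries. Of the log2 fold changes, GC content and length accounted for an R squared of 0.113 at 2 h, 0.00357 at 6 h and 0.033 at 20 h against 0 h, and of 0.234 between 20 and 2 h.

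**Figure D1:**
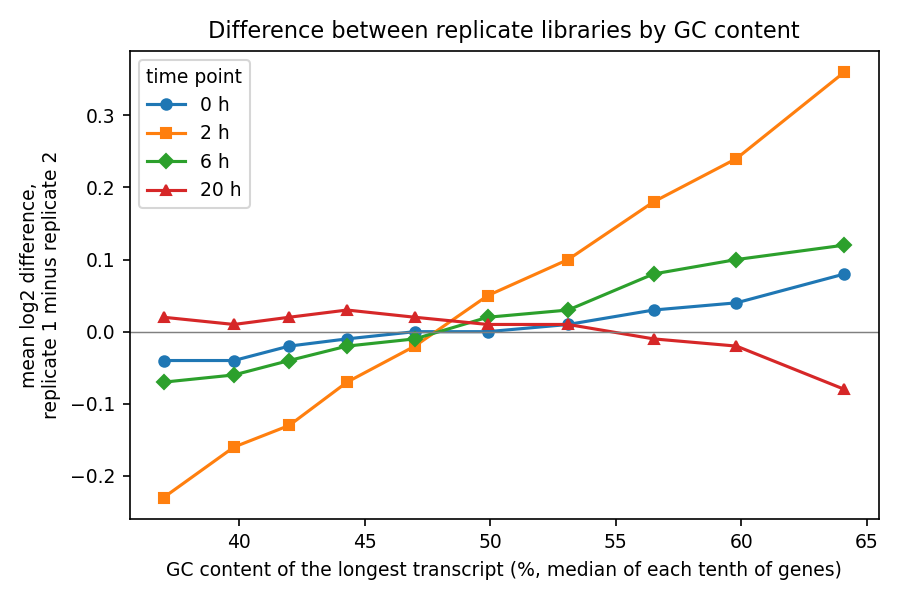
Mean log2 difference between replicate 1 and replicate 2 (vertical axis) in 10 equal classes of genes ordered by the GC content of their longest transcript (horizontal axis, class median in %), 1 line per time point. At 2 h the difference runs from -0.23 in the class with a median of 37% GC to 0.36 in the class with a median of 64.1% GC.

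The transcripts of the receptor and of its pathway were examined first. LTBR itself was at 94.7 ± 2.9 CPM (SD, n = 2) at 0 h and at 101 ± 16, 93.5 ± 3.6 and 90.7 ± 1.3 CPM at 2, 6 and 20 h, with adjusted p of 0.714, 0.994 and 0.8 against 0 h. EWSR1, an RNA-binding protein, was at 181 ± 1.5 CPM at 0 h and 202 ± 7.3 CPM at 20 h, with an adjusted p of 0.273. NFKB2, the precursor of the p52 subunit, rose from 28.0 ± 0.49 CPM to 51.0 ± 7.6, 82.6 ± 6.3 and 57.7 ± 0.2 CPM, log2 fold changes of 0.86, 1.56 and 1.04. RELB, the partner of p52, rose from 8.29 ± 0.59 to 31.7 ± 3.8 CPM at 6 h (log2 fold change 1.94 ± 0.13 SE, adjusted p = 8.7e-07). TRAF3, an adaptor that holds back the noncanonical pathway, changed by 0.33 ± 0.08 at 2 h (adjusted p = 0.0586) and rose by 0.69 ± 0.08 at 6 h and 0.55 ± 0.08 at 20 h. MAP3K14, the NF-κB-inducing kinase, rose at all 3 times, most at 2 h with 1.14 ± 0.10. The calls of TRAF3 at 20 h and MAP3K14 at 6 h were lost without 0 h replicate 1 (adjusted p of 0.0562 and 0.129). That of MAP3K14 at 20 h was lost without either 0 h library or 20 h replicate 2 (adjusted p of 0.0507 to 0.256).

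**Figure D2:**
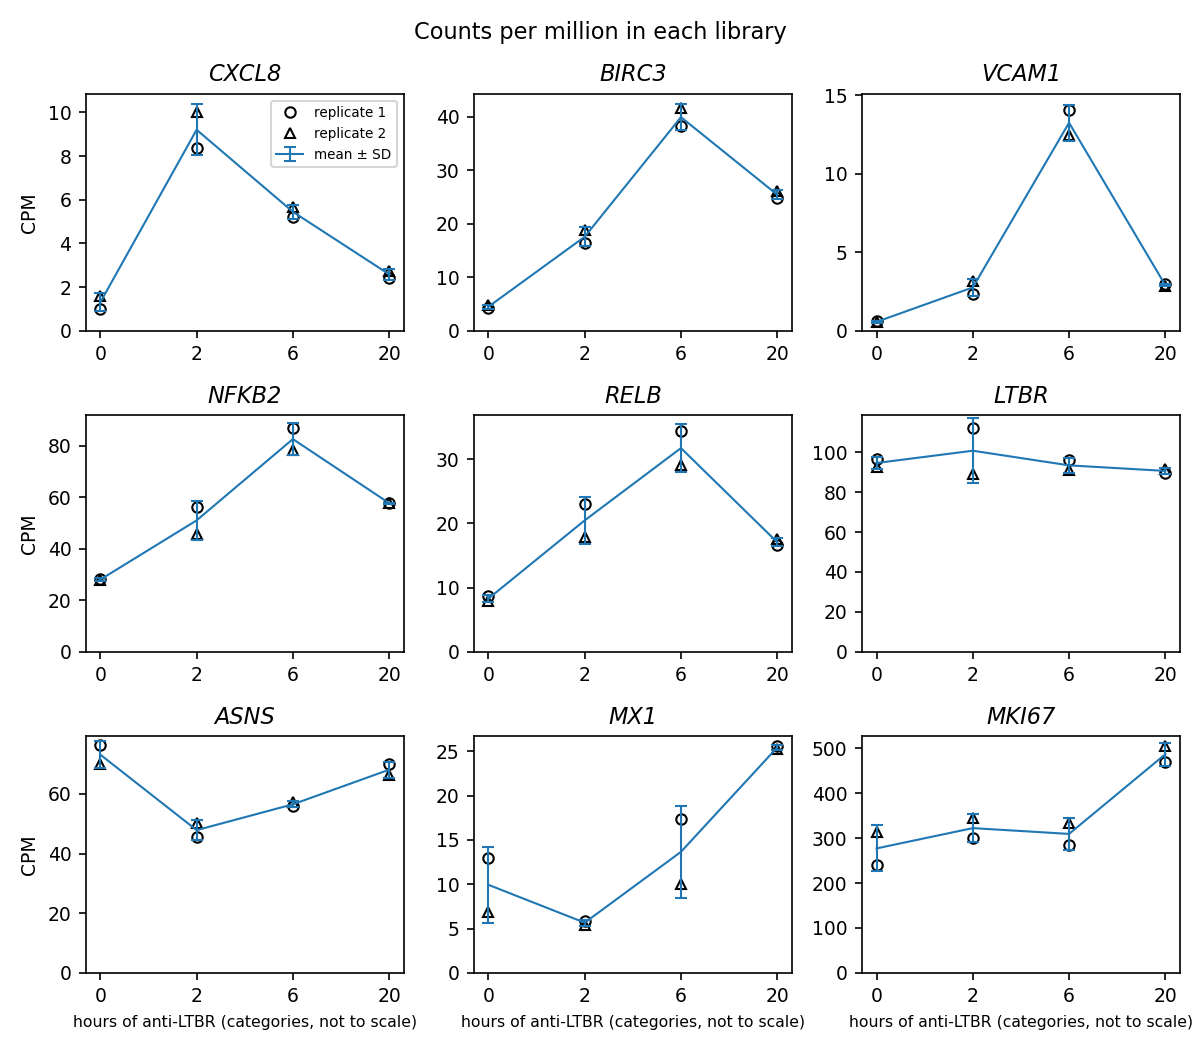
Levels in CPM (vertical axes, from 0) of 9 genes at 0, 2, 6 and 20 h (horizontal axes, drawn as categories), with a symbol for each library and the mean ± SD of the 2 libraries as a line with error bars. CXCL8 has its highest mean, 9.21 CPM, at 2 h, VCAM1 its highest, 13.3 CPM, at 6 h, and MKI67 its highest, 487 CPM, at 20 h.

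The comparison of 2 h with 0 h addressed the early response. Chemokine genes led it: CXCL8, which attracts neutrophils, rose 6.94-fold from 1.30 ± 0.42 to 9.21 ± 1.2 CPM (SD, n = 2), and CXCL1 rose 6.6-fold to 12.7 ± 0.26 CPM. The survival gene BIRC3 rose 3.9-fold, the NF-κB feedback regulators TNFAIP3 and NFKBIA 3.4-fold and 2.85-fold, and the cytokine gene IL6 3.33-fold. CCL2, a monocyte chemokine, rose 3.01-fold from 35.8 ± 2.2 to 108 ± 2.6 CPM. The genes that fell included CHAC1 (glutathione degradation), with a log2 fold change of -1.20 ± 0.25 SE, the potassium channel gene KCNJ2 with -1.17 ± 0.20 and SPRY1, an inhibitor of growth factor signalling, with -1.01 ± 0.20. The 2 h libraries of CHAC1 stood at 11.8 and 4.75 CPM, against 18.9 and 18.6 CPM at 0 h. The calls of KCNJ2 and SPRY1 were lost without either 0 h library, at adjusted p of 0.0834 to 0.297 and 0.137 to 0.443. That of CHAC1 was lost without any 1 of the 0, 6 or 20 h libraries, at 0.126 to 0.468. It was also lost with the library code series as a block (adjusted p of 0.264), with DESeq2 (0.182), with the 4 libraries compared alone (0.636) and with a stricter low-count filter (0.0639).

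By gene list, 7 of 17 NF-κB subunits and feedback regulators rose at 2 h and 0 fell (12 rose when adjusted over the list alone), with a camera adjusted p of 6.85e-43, and adjusted p = 0.0112 with an estimated correlation. Of 12 chemokines tested, 4 rose (8 adjusted over the list alone; adjusted p = 0.00468 with an estimated correlation): CCL2, CXCL1, CXCL3 and CXCL8. CXCL3 had 4 and 1 counts in the 0 h libraries, too few for a firm fold. Of 12 cytokines and colony-stimulating factors, 3 rose (6 adjusted over the list alone), IL6, LIF and CSF1, and of 13 receptor pathway components 2 rose (4 adjusted over the list alone), BIRC3 and MAP3K14. Both lists had adjusted p = 0.0189 with an estimated correlation. VCAM1 and ICAM1, adhesion molecules for leukocytes, were the 2 of 8 lymphoid stromal organiser genes that rose (2 adjusted over the list alone; adjusted p = 0.0195, and adjusted p = 0.224 with an estimated correlation). Without 0 h replicate 2 and without 2 h replicate 2 the adjusted p of that list was 0.111 and 0.124. IRAK2 and TICAM1 were the 2 of 17 innate sensors and signalling genes that rose (2 adjusted over the list alone; adjusted p = 0.0829 for the list). Of 26 immediate-early genes 4 rose (7 rose and 2 fell adjusted over the list alone), JUNB by 1.19 ± 0.14, FOSL1 by 0.63 ± 0.09, IER3 by 0.60 ± 0.13 and KLF10 by 0.48 ± 0.09. The immediate-early list had an adjusted p of 0.0379, and adjusted p = 0.812 with an estimated correlation, and its median against 0 h was 0.14 in 2 h replicate 1 and -0.09 in 2 h replicate 2. Its adjusted p was 0.313 without 0 h replicate 2, 0.626 in the other direction without 2 h replicate 1, and 0.257 with the GC and length trend removed. Of 17 apoptosis regulators BIRC3 alone rose (2 adjusted over the list alone; adjusted p = 0.0053, and adjusted p = 0.24 with an estimated correlation). The adjusted p of the apoptosis list was 0.0576 without 0 h replicate 2 and 0.161 without 2 h replicate 2. Among the genes named here, the calls of CXCL3, TICAM1 and KLF10 were lost without either 0 h library (adjusted p of 0.0638 to 0.521) and that of FOSL1 without 0 h replicate 1 (0.114). The call of IER3 was lost without either 0 h library, 2 h replicate 1 or either 20 h library (0.0523 to 0.375), and with a stricter low-count filter or limma-voom (0.05 to 0.0593).

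Genes of endoplasmic reticulum and amino acid stress were lower at 2 h. Of 17, 6 fell and 0 rose (12 fell when adjusted over the list alone), with a median log2 fold change of -0.36 and a camera adjusted p of 2.99e-17, and adjusted p = 0.0903 with an estimated correlation and 0.0248 with fry. Besides CHAC1 these included the asparagine synthetase gene ASNS at -0.61 ± 0.08 SE, the cystine transporter gene SLC7A11 at -0.59 ± 0.09 and the lipoprotein receptor gene VLDLR at -0.61 ± 0.09. Without 0 h replicate 1 all 4 of these calls were lost, at 0.0652 for ASNS and 0.197 for VLDLR, and that of SLC7A11 was lost without either 0 h library (adjusted p of 0.105 to 0.149). PSAT1, a serine synthesis gene, and TRIB3, both named after their values were seen, fell as well (adjusted p of 0.000698 and 0.0449). The call of PSAT1 was not lost in any alternative. That of TRIB3 was lost without either 0 h or 20 h library. It was also lost with a stricter low-count filter, with limma-voom and with the 4 libraries compared alone. The list median against 0 h was -0.21 in 2 h replicate 1 and -0.45 in 2 h replicate 2. ASNS went from 73.2 ± 4.6 CPM at 0 h to 47.9 ± 3.5 at 2 h, 56.5 ± 0.99 at 6 h and 68.1 ± 2.7 at 20 h. It was higher at 20 h than at 2 h by 0.51 ± 0.08 (adjusted p = 0.00387, and 0.0583 without 20 h replicate 1). At 6 h ASNS, VLDLR and PSAT1, 3 of the 17 genes, fell (5 adjusted over the list alone). The list then had an adjusted p of 0.00114, and adjusted p = 0.357 with an estimated correlation, and 0.0643 without 0 h replicate 1. The 6 h call of ASNS was lost without any 1 of the 0, 6 or 20 h libraries (0.088 to 0.617) and with total counts for scaling (0.0545). That of VLDLR was lost without any 1 of the 4 libraries compared (0.0835 to 0.507) and that of PSAT1 without 0 h replicate 1 (0.101). At 20 h edgeR called 0 of them (3 adjusted over the list alone, 9 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom), with an adjusted p of 0.000207 for the list, and adjusted p = 0.375 with an estimated correlation.

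In all, edgeR called 99 genes higher and 48 lower at 2 h than at 0 h, of 14289 tested, with 23 and 5 of them changed at least 2-fold, and 1826 genes had an unadjusted p under 0.05. Over all genes tested, called or not, the 2 groups of libraries did not overlap in 38% of genes (38.6% at 6 h and 55% at 20 h against 0 h), where chance gives 33.3%. The counts were 30 higher and 4 lower without 0 h replicate 1, 34 and 7 without 0 h replicate 2, and 1430 and 973 without 2 h replicate 2. Of 39 calls of named genes at 2 h, 17 were kept without 0 h replicate 1 and 20 without 0 h replicate 2. Without 2 h replicate 1, the library with the strong GC trend, the named calls lost were those of PMAIP1, TXNIP and IER3. Without 2 h replicate 2 only that of TXNIP was lost. With the GC and length trend of each library removed, a setting chosen after the data were seen, 249 were higher and 193 lower, 143 of the 147 genes among them. CHAC1 then changed by -1.37 ± 0.27 (adjusted p = 0.0582, from -1.20 ± 0.25) and TXNIP by -0.64 ± 0.19 (adjusted p = 0.165, from -0.69 ± 0.13). The robust fit gave CHAC1 5.95 degrees of freedom in place of 14.2, which took its unadjusted p to 0.00217, where 14.2 would have given 0.000142. For TXNIP the standard error grew and the degrees of freedom fell from 14.2 to 5.79.

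The comparison of 6 h with 0 h addressed the response at its intermediate time. VCAM1 rose 23.4-fold, from 0.565 ± 0.057 to 13.3 ± 1.1 CPM (SD, n = 2), and BIRC3 8.86-fold, from 4.49 ± 0.36 to 39.9 ± 2.4 CPM. SOD2, the mitochondrial superoxide dismutase, rose 3.59-fold to 158 ± 23 CPM, and TRAF1, a signalling adaptor, 3.08-fold to 11.6 ± 0.8 CPM. ICAM1 rose 2.55-fold to 144 ± 12 CPM, C3 of complement 2.53-fold and PTGS2, the inducible cyclooxygenase, 1.64-fold. The genes that fell included PPL (periplakin) with a log2 fold change of -1.53 ± 0.27 SE, the stem cell factor receptor gene KIT with -0.67 ± 0.10, TXNIP, which inhibits thioredoxin, with -0.70 ± 0.14, and the Hedgehog receptor gene PTCH1 with -0.57 ± 0.10. These 4 calls were lost without some libraries. For PPL these were 0 h replicate 1 and either 6 h library (adjusted p of 0.0504 to 0.323), and for KIT 0 h replicate 2 (0.0926). For TXNIP they were 0 h replicate 1, 6 h replicate 2 and either 2 h library (0.0682 to 0.564), and for PTCH1 either 0 h library and 6 h replicate 2 (0.135 to 0.179).

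By list, 8 of 17 NF-κB subunits and feedback regulators rose at 6 h (11 adjusted over the list alone; adjusted p = 0.00298 with an estimated correlation). Of the chemokines 6 of 12 rose (8 adjusted over the list alone), including CXCL6 at 2.50 ± 0.33 SE. Of the cytokines 6 of 12 rose (7 adjusted over the list alone), including IL34, a ligand of the CSF1 receptor, at 2.79 ± 0.41 and IL32 at 1.40 ± 0.15. Of the receptor pathway components 5 of 13 rose (6 adjusted over the list alone), TRAF1, TRAF3, BIRC2, BIRC3 and MAP3K14. These 3 lists each had adjusted p = 0.00222 with an estimated correlation. IL34 was at 0.164 ± 0.042 CPM at 0 h, with 4 and 7 counts, and at 1.18 ± 0.11 CPM at 6 h. VCAM1 and ICAM1 were again the 2 lymphoid stromal organiser genes that rose (2 adjusted over the list alone; adjusted p = 0.00768 with an estimated correlation), while the list median was -0.04 against a mean of 0.58. Of the apoptosis regulators 3 of 17 rose (5 adjusted over the list alone; adjusted p = 0.0185 with an estimated correlation), BIRC3, TNFAIP8 and CFLAR. The antigen transporter gene TAP1 was the 1 of 18 genes of MHC class I presentation that rose (2 adjusted over the list alone), by 0.54 ± 0.08. That list had an adjusted p of 0.000169, and adjusted p = 0.325 with an estimated correlation. The calls of CXCL6 and TAP1 were lost without 0 h replicate 2 (adjusted p of 0.0527 and 0.0761), and that of IL34 without either 0 h library (0.065 to 0.113). The call of CFLAR was lost without either 0 h library or 6 h replicate 1 (0.131 to 0.177), and that of TNFAIP8 without any 1 of the 4 libraries compared (0.104 to 0.26).

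Of the innate sensors, IRAK2 was the 1 of 17 that rose at 6 h (1 adjusted over the list alone; adjusted p = 0.00502, and adjusted p = 0.281 with an estimated correlation, and 0.0976 without 0 h replicate 1). SOD2 and PTGS2 were the 2 of 11 prostaglandin and superoxide enzymes that rose (3 rose and 1 fell adjusted over the list alone; adjusted p = 7.17e-06, and adjusted p = 0.0997 with an estimated correlation). Of the immediate-early genes FOSL1, JUNB and MYC, 3 of 26, rose (3 adjusted over the list alone; adjusted p = 0.000864, and adjusted p = 0.57 with an estimated correlation, and 0.0526 without 0 h replicate 2). The call of FOSL1 was lost without either 0 h library (adjusted p of 0.0544 to 0.16), and those of JUNB and MYC without any 1 of the 4 libraries compared (0.0706 to 0.413). At 6 h, edgeR called 133 genes higher and 31 lower than at 0 h, with 38 and 3 of them changed at least 2-fold and 1114 genes at an unadjusted p under 0.05. The counts were 41 and 1 without 0 h replicate 1, 48 and 6 without 0 h replicate 2, 67 and 14 without 6 h replicate 1 and 74 and 6 without 6 h replicate 2. They were 269 and 155 without 2 h replicate 1 and 267 and 155 without 2 h replicate 2. With the GC and length trend removed they were 330 and 243, with 159 of the 164 genes among them. The call of TXNIP ended there (-0.69 ± 0.19, adjusted p = 0.148, from -0.70 ± 0.14) and with the 4 libraries compared alone (adjusted p = 0.0551). Of 46 calls of named genes at 6 h, 24 were kept without 0 h replicate 1, 25 without 0 h replicate 2, 35 without 6 h replicate 1 and 30 without 6 h replicate 2.

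The comparison of 20 h with 0 h addressed the late response. BIRC3 was still 5.63-fold higher at 25.4 ± 0.87 CPM (SD, n = 2), CXCL1 2.93-fold, TNFAIP3 2.41-fold and RELB 2.06-fold. Of 31 cell cycle genes 20 rose (adjusted p = 0.0884 for the list with an estimated correlation, and 0.0165 with fry). MKI67, a marker of dividing cells, went from 277 ± 51 to 487 ± 26 CPM, and the mitotic genes CENPF, BUB1B and BUB1 rose by log2 fold changes of 0.83 ± 0.12 SE, 0.79 ± 0.11 and 0.77 ± 0.11. Without 0 h replicate 1 the calls of these 4 genes were lost, at adjusted p of 0.0547, 0.101, 0.0641 and 0.0692. Of 36 interferon-stimulated genes 17 rose (adjusted p = 0.186 for the list with an estimated correlation, and 0.0498 with fry). The antiviral gene MX1 went from 9.93 ± 4.3 to 25.4 ± 0.26 CPM, a call lost without 0 h replicate 2, either 2 h library or either 20 h library (adjusted p of 0.0709 to 0.156). OAS2 went from 4.38 ± 0.7 to 10.2 ± 0.37 CPM, a call lost without either 0 h library (adjusted p of 0.0967 and 0.12). LRIG1, a negative regulator of receptor tyrosine kinases, rose 2.11-fold. The genes that fell included CLEC3B (tetranectin) with -1.02 ± 0.14, ACKR3, a scavenging chemokine receptor, with -0.93 ± 0.13, and SEMA3B with -0.85 ± 0.13. Without 0 h replicate 1 the calls of CLEC3B and SEMA3B were lost, at adjusted p of 0.0608 and 0.0967.

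The 20 cell cycle genes that rose at 20 h stood against 0 that fell (28 rose when adjusted over the list alone), with a median log2 fold change of 0.55, a camera adjusted p of 4.93e-47, and adjusted p = 0.0884 with an estimated correlation. At 2 and 6 h edgeR called 0 of the 31 (3 and 0 adjusted over the list alone, 10 and 0 at an unadjusted p under 0.05, 1 and 0 by DESeq2, 0 and 0 by limma-voom). The list nonetheless had adjusted p of 3.34e-07 and 0.00502, and adjusted p = 0.577 and 0.727 with an estimated correlation. At 6 h the adjusted p of the cell cycle list was 0.326 without 0 h replicate 1 and 0.639, in the other direction, without 6 h replicate 2. The 17 interferon-stimulated genes that rose at 20 h stood against 0 that fell (24 rose and 2 fell adjusted over the list alone), with a median of 0.43, an adjusted p of 2.74e-17, and adjusted p = 0.186 with an estimated correlation. At 6 h IRF1, DDX58 and IFIH1 rose (9 adjusted over the list alone; adjusted p = 3.24e-07, and adjusted p = 0.357 with an estimated correlation, and 0.13 without 6 h replicate 1). Of these, IRF1 and DDX58 were lost without either 0 h library or 6 h replicate 1 (adjusted p of 0.0503 to 0.218) and IFIH1 without 0 h replicate 2 or 6 h replicate 1 (0.0894 to 0.22). At 2 h IRF1 rose and XAF1 fell (1 and 3 adjusted over the list alone), both named after their values were seen. The call of XAF1 was lost without either 0 h library (0.234 to 0.461) and with a stricter low-count filter (0.0508). The list was lower at 2 h, with an adjusted p of 0.000169, and adjusted p = 0.577 with an estimated correlation, and it was 0.0686 without 0 h replicate 1 and 0.0586 without 2 h replicate 2. Between 20 h and 2 h, 21 of the 36 were higher and 1 lower, with a camera adjusted p of 6.15e-31, and adjusted p = 0.3 with an estimated correlation. MX1 was at 13.0 and 6.88 CPM in the 0 h libraries and at 17.3 and 9.99 CPM in the 6 h libraries.

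**Figure D3:**
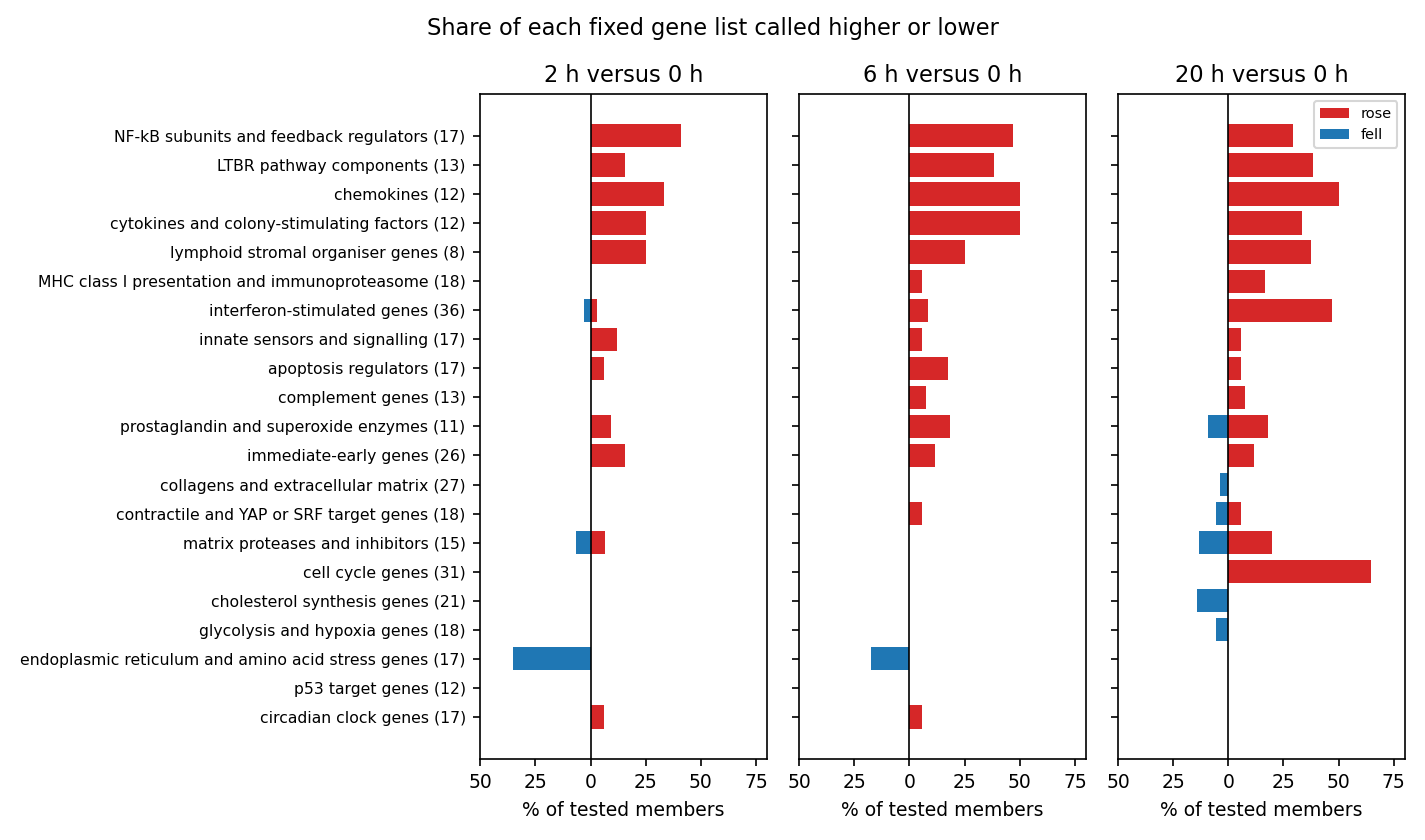
Percentage of the tested members of 21 gene lists (number tested in parentheses) called higher (to the right) or lower (to the left) at 2, 6 and 20 h against 0 h at an adjusted p under 0.05. At 20 h 20 of 31 cell cycle genes and 17 of 36 interferon-stimulated genes rose, and at 2 h 6 of 17 genes of endoplasmic reticulum and amino acid stress fell.

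At 20 h, 5 of 17 NF-κB subunits and feedback regulators rose (7 adjusted over the list alone), NFKB2, RELB, NFKBIA, NFKBIE and TNFAIP3. Of 12 cytokines IL6, IL32, IL34 and LIF rose (4 rose and 1 fell adjusted over the list alone), each list with adjusted p = 0.0464 with an estimated correlation. Of 12 chemokines 6 rose (7 adjusted over the list alone) and of 13 receptor pathway components the same 5 rose as at 6 h (6 adjusted over the list alone), each with adjusted p = 0.0262 with an estimated correlation. Without 0 h replicate 1 the calls of IL34 (adjusted p of 0.0608), LIF and TRAF1 were lost, that of LIF also without 20 h replicate 2 (0.199 to 0.3) and that of TRAF1 without 0 h replicate 2 or 20 h replicate 2 (0.0562 to 0.0947). Besides VCAM1 and ICAM1, CXCL12 rose among the 8 lymphoid stromal organiser genes (3 rose and 2 fell adjusted over the list alone), by 0.26 ± 0.07 SE. The call of CXCL12 was lost without any 1 of the 0, 6 or 20 h libraries (0.0667 to 0.434) and with total counts for scaling (0.0563). That of ICAM1 (adjusted p = 0.0491) was lost without any 1 of the 4 libraries compared (0.115 to 0.348), with a stricter low-count filter, with limma-voom and on the deposited log2 values (0.0526 to 0.0657). The list had an adjusted p of 0.0876, with a median of -0.03 against a mean of 0.18. TAP1, TAP2 and PSME2 were the 3 of 18 MHC class I genes that rose (4 adjusted over the list alone; adjusted p = 0.00509, and adjusted p = 0.53 with an estimated correlation, and 0.123 without 0 h replicate 2). These 3 calls were lost without either 0 h library or 20 h replicate 2, those of TAP1 and PSME2 also without 20 h replicate 1 and that of PSME2 without either 6 h library (0.0609 to 0.349). IRAK2 was again the 1 of 17 innate sensors that rose (1 adjusted over the list alone), and FOSL1, KLF6 and KLF10 were the 3 of 26 immediate-early genes that rose (6 rose and 2 fell adjusted over the list alone), where DESeq2 called 6 and limma-voom 2. The call of IRAK2 was lost without 0 h replicate 1 or either 20 h library (0.0595 to 0.178), and those of KLF6 and KLF10 without any 1 of the 4 libraries compared (0.123 to 0.476). That of KLF10 (adjusted p = 0.0489) was also lost with either other scaling, a stricter low-count filter, limma-voom and the deposited log2 values (0.0517 to 0.0628). BIRC3 was the 1 of 17 apoptosis regulators that rose (1 adjusted over the list alone; adjusted p = 0.00232, and adjusted p = 0.186 with an estimated correlation). Of 21 cholesterol synthesis genes 3 fell (16 adjusted over the list alone), MVD by 0.43 on the log2 scale, DHCR7 by 0.39 and MSMO1 by 0.34. All 3 calls were lost without any 1 of the 4 libraries compared (0.0777 to 0.399). The cholesterol list had an adjusted p of 1.1e-10, and adjusted p = 0.0761 with an estimated correlation and 0.00993 with fry. It was also lower at 2 and 6 h with 0 members called by edgeR (1 and 0 adjusted over the list alone, 4 and 6 at an unadjusted p under 0.05, 1 and 0 by DESeq2, 0 and 0 by limma-voom). The adjusted p at these times were 0.0053 and 2.53e-06, and adjusted p = 0.418 and 0.123 with an estimated correlation and 0.177 and 0.0498 with fry.

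At 20 h, edgeR called 402 genes higher and 191 lower than at 0 h, with 28 and 8 of them changed at least 2-fold and 2466 genes at an unadjusted p under 0.05. The counts were 55 and 10 without 0 h replicate 1, 163 and 38 without 0 h replicate 2, 199 and 54 without 20 h replicate 1 and 116 and 19 without 20 h replicate 2. They were 965 and 699 without 2 h replicate 1 and 976 and 683 without 2 h replicate 2. With the GC and length trend removed they were 1232 and 784, with 569 of the 593 genes among them. MX1 then changed by 1.40 ± 0.36 (adjusted p = 0.0717, from 1.37 ± 0.24) and TXNIP by -0.52 ± 0.18 (adjusted p = 0.13, from -0.51 ± 0.13), with larger standard errors and with 4.73 and 5.79 degrees of freedom in place of 14.2. Of 71 calls of named genes at 20 h, 17 were kept without 0 h replicate 1, 36 without 0 h replicate 2, 43 without 20 h replicate 1 and 32 without 20 h replicate 2. Unstimulated cells kept for 2, 6 or 20 h were not analysed here, so each difference from 0 h also holds the time in culture. None of the 8 libraries came from cells given a control antibody, so an effect of the receptor cannot be told apart from one of adding an antibody.

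The stimulated time points were also compared directly. From 2 to 6 h VCAM1 rose further by a log2 fold change of 2.25 ± 0.15 SE, SOD2 by 0.93 ± 0.09 and NFKB2 by 0.70 ± 0.10, while CXCL8 fell by 0.76 and CXCL1 by 0.59. From 6 to 20 h VCAM1 changed by -2.19 ± 0.15, SOD2 by -1.23 ± 0.10, IL6 by -0.99 ± 0.09, ICAM1 by -0.98 ± 0.10 and RELB by -0.89 ± 0.12, while CENPF rose by 0.70 ± 0.12 and MKI67 by 0.65 ± 0.11. The falls of CXCL8 and CXCL1 from 2 to 6 h were lost as calls without any 1 of the 0, 6 or 20 h libraries (adjusted p of 0.0676 to 0.413) and with the 4 libraries compared alone (0.191 and 0.229). That of CXCL8 was also lost with a stricter low-count filter (0.0537), and the rise of NFKB2 with the 4 libraries alone (0.091). Without 6 h replicate 1 or 20 h replicate 2 the changes from 6 to 20 h of RELB (0.0589 to 0.0684), CENPF and MKI67 (0.15 to 0.175) were not called. IL34 differed by 0.05 ± 0.27 between 20 and 6 h, with an adjusted p of 0.976. Chemokines as a list were lower at 20 h than at 6 h (1 higher and 3 lower of 12), with a median of -0.54 and adjusted p = 0.0385 with an estimated correlation. edgeR called 52 genes higher and 27 lower at 6 h than at 2 h, 127 and 44 at 20 h than at 6 h, and 286 and 303 at 20 h than at 2 h. At 6 h against 2 h the counts were 21 and 7 without either 0 h library, 16 and 6 without 6 h replicate 1, 28 and 6 without 6 h replicate 2, and 974 and 1196 without 2 h replicate 2. At 20 h against 6 h they were 52 and 20 without either 0 h library, 4 and 6 without 6 h replicate 1, and 41 and 7 without 20 h replicate 1. They were 366 and 274 without 2 h replicate 1 and 377 and 255 without 2 h replicate 2. Without 20 h replicate 2, edgeR called 0 genes higher at 20 h than at 6 h, with 419 at an unadjusted p under 0.05, and 5 lower. At 20 h against 2 h they were 143 and 117 without 0 h replicate 1, 142 and 117 without 0 h replicate 2, 79 and 28 without 20 h replicate 1 and 36 and 42 without 20 h replicate 2. They were 216 and 170 without 2 h replicate 1 and 2146 and 2222 without 2 h replicate 2.

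Over the whole course, 625 genes differed among the 4 time points, of which 110 had their highest fitted level at 0 h, 138 at 2 h, 112 at 6 h and 265 at 20 h. This number was 191 without 0 h replicate 1, 262 without 0 h replicate 2, 290 without 20 h replicate 1, 239 without 20 h replicate 2, 1327 without 2 h replicate 1 and 4113 without 2 h replicate 2. At all 3 times 29 genes were higher than at 0 h, including BIRC3, VCAM1, CXCL1, CXCL8, CCL2, IL6, LIF, NFKB2, RELB, NFKBIA, TNFAIP3, SOD2 and ICAM1, and 6 were lower, including KIT, TXNIP and B3GALT2. Of the 13 higher genes named here, 4 lost their call at 20 h in some settings. For CXCL8 these were the fits without 0 h replicate 1 or either 20 h library (0.0709 to 0.354) and on the deposited log2 values (0.126), and for SOD2 those without either 0 h library (0.0608 to 0.0653). LIF was lost without 0 h replicate 1 or 20 h replicate 2 (adjusted p of 0.199 to 0.3), and ICAM1 in the 7 settings described above (0.0526 to 0.348). KIT was lost at 2 and 6 h without 0 h replicate 2 (0.148 and 0.0926), and B3GALT2 at all 3 times without 0 h replicate 1 at 2 and 6 h without 0 h replicate 2, and at 6 h without either 6 h library (0.0698 to 0.62). The calls of TXNIP at all 3 times ended with the GC and length trend removed (adjusted p of 0.165, 0.148 and 0.13). Its log2 fold changes were then -0.64, -0.69 and -0.52, from -0.69, -0.70 and -0.51. The 2 h call of TXNIP was also lost without 0 h replicate 1 or either 2 h library. Its 20 h call was lost without 0 h replicate 1 or either 2 h or 20 h library, and with a stricter low-count filter or limma-voom. The higher genes shared 45 between 2 and 6 h, 33 between 2 and 20 h and 71 between 6 and 20 h, where independent lists would share 0.92, 2.8 and 3.7. The lower genes shared 10, 16 and 24, where independent lists would share 0.1, 0.64 and 0.41. The 3 comparisons use the same 0 h libraries, so part of this excess may come from them. In 20 simulations all 8 libraries were drawn anew at the 0 h means, with genes independent, and at most 1 call was shared. These draws lack the actual deviations of the 0 h libraries, so they do not show how much of the excess comes from them. Over genes, log2 fold changes at 2 and 6 h, 2 and 20 h, and 6 and 20 h correlated at 0.607, 0.494 and 0.634, against 0.514, 0.52 and 0.521 in the simulations, and their covariances were 0.0436, 0.0401 and 0.0507 against 0.0216, 0.0216 and 0.0219.

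The remaining lists held few called genes. Of 13 complement genes C3 rose at 6 and 20 h, by 1.34 ± 0.16 SE and 0.63 ± 0.16 on the log2 scale. Adjusted over the list alone, 1 rose at each of these times, while 2 fell at 2 h and 2 at 20 h. The 20 h call of C3 was lost without any 1 of the 4 libraries compared (adjusted p of 0.12 to 0.327), with a stricter low-count filter, with limma-voom and on the deposited log2 values (0.054 to 0.0617). Among the 11 prostaglandin and superoxide enzymes, SOD2 rose at 2 h, and at 20 h PTGS2 and SOD2 rose and PTGS1 fell (3 rose and 2 fell adjusted over the list alone). At 20 h the call of PTGS2 was lost without 0 h replicate 1 (0.0698), that of SOD2 without either 0 h library (0.0608 to 0.0653) and that of PTGS1 without any 1 of the 0, 6 or 20 h libraries (0.055 to 0.427). THBS2 (thrombospondin 2) was the 1 of 27 collagen and matrix genes that edgeR called against 0 h, falling by 0.37 on the log2 scale at 20 h (1 rose and 3 fell adjusted over the list alone), and the list had an adjusted p of 0.0506. DESeq2 called 1 of the 27 at 2 h and 4 at 20 h, and limma-voom 0 and 1. Among 18 contractile and YAP or SRF target genes, ANKRD1 rose at 6 h. CTGF fell and ANKRD1 rose at 20 h (1 rose and 5 fell adjusted over the list alone; adjusted p = 0.0242, and adjusted p = 0.605 with an estimated correlation, 0.0862 without 0 h replicate 1 and 0.0508 without 20 h replicate 1). Among 15 matrix proteases and inhibitors 3 rose and 2 fell at 20 h (3 and 3 adjusted over the list alone). MMP1 changed by 0.41 ± 0.08 SE, PLAU by 0.39 ± 0.07, ADAMTS5 by -0.43 ± 0.09 and ADAMTS1 by -0.35 ± 0.07. The 20 h calls of THBS2, CTGF, MMP1, PLAU and ADAMTS1 were lost without any 1 of the 4 libraries compared (0.0686 to 0.362), and that of ADAMTS5 without either 0 h library or 20 h replicate 2 (0.117 to 0.268). ANKRD1 was lost at 6 and 20 h without any 1 of the 0, 6 or 20 h libraries (0.0522 to 0.61), and at 6 h also with total counts for scaling and a stricter low-count filter (0.0501 to 0.0512). At 2 h PLAU rose and ADAMTS5 fell. That call of ADAMTS5 was lost without either 0 h library (0.218 to 0.24), and that of PLAU without either 0 h or 20 h library (0.0513 to 0.232) and with the 4 libraries compared alone (0.0957). NDRG1 was the 1 of 18 glycolysis and hypoxia genes that edgeR called, falling by 0.41 at 20 h, where DESeq2 called 2 and limma-voom 1. That call was lost without either 0 h library or 20 h replicate 2 (0.0675 to 0.399). The clock genes NPAS2 and BHLHE40 were the 2 of 17 that rose, at 6 h by 0.50 ± 0.08 and at 2 h by 0.45 ± 0.09. NPAS2 was lost without either 0 h library or 6 h replicate 1 (0.106 to 0.135), and BHLHE40 without either 0 h or 20 h library (0.0706 to 0.341) and with the 4 libraries compared alone (0.103). Of 12 p53 target genes edgeR called 0 at 2, 6 and 20 h, with 2, 1 and 3 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. Of 12 fibroblast markers edgeR called 0 at 2, 6 and 20 h (2, 0 and 2 fell adjusted over the list alone), with 2, 1 and 4 at an unadjusted p under 0.05, 1, 0 and 2 by DESeq2 and 0 by limma-voom. The fibroblast list was lower at 20 h with an adjusted p of 0.018, and adjusted p = 0.605 with an estimated correlation, 0.308 without 0 h replicate 1 and 0.052 without 20 h replicate 2. Median, mean and test differed in sign, with no list call, for the collagen list at 2 h, the contractile list at 2 and 6 h, complement at 6 h, proteases at 20 h, and clock genes at 2, 6 and 20 h.

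Markers of other cell types were examined as well. The filter left 4 of 12 keratinocyte, 4 of 10 endothelial, 2 of 8 melanocyte, 4 of 12 leukocyte, 10 of 10 pericyte and smooth muscle and 4 of 8 adipocyte markers, and edgeR called 0 of them against 0 h, as did DESeq2 and limma-voom. At an unadjusted p under 0.05 were 1 keratinocyte marker at 2 h, 2 pericyte markers at 2 h and 4 at 20 h, and 1, 2 and 3 adipocyte markers at 2, 6 and 20 h. Median, mean and test differed in sign for keratinocyte markers at 2 and 6 h, endothelial and pericyte markers at 2 h and adipocyte markers at 2 and 20 h. Adjusted over the list alone, 1 pericyte marker rose at 2 h, 1 rose and 1 fell at 20 h, and 1 adipocyte marker rose and 2 fell at 20 h.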

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

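The differences below come from planned comparisons between stimulated time points, but both genes were picked after their values were seen. They were picked because each was called in opposite directions at 2 times against 0 h and the difference between those times was itself called. The called difference was thus a condition of the choice and gives no separate support. APOL6 changed by -0.39 ± 0.07 SE on the log2 scale at 2 h (adjusted p = 0.0153 in edgeR) and by 0.33 ± 0.07 at 6 h (adjusted p = 0.0333), a difference of 0.73 ± 0.07 (adjusted p = 0.00015). XAF1 changed by -0.49 ± 0.10 at 2 h (adjusted p = 0.0344) and by 0.39 ± 0.10 at 20 h (adjusted p = 0.0388), a difference of 0.88 ± 0.10 (adjusted p = 0.000458). The calls against 0 h at 2 h were lost without 0 h replicate 1 and without 0 h replicate 2, for both genes. The call of APOL6 at 6 h was lost without either 0 h, 6 h or 20 h library, and that of XAF1 at 20 h without either 0 h or 20 h library. The call of APOL6 at 2 h was also lost with the 4 libraries compared alone (adjusted p = 0.0896), and those of XAF1 at 2 and 20 h with a stricter low-count filter (0.0508 and 0.052). Over all 20 alternatives the difference stayed called, between 0.48 and 0.77 for APOL6 and between 0.51 and 0.98 for XAF1, with adjusted p of at most 0.0155 and 0.0106.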

How the results depend on the processing

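The setting with GC content and length removed and the one on the deposited log2 values were chosen after the data were seen. Of 156 calls of named genes against 0 h, 53 held in every alternative other than the stricter threshold, 103 were lost in at least 1 that left out a library, and 0 turned in direction. Those that held at all 3 times include BIRC3, VCAM1, CXCL1, CCL2, IL6, NFKB2, RELB, NFKBIA and TNFAIP3. Of 103 other calls, mostly between stimulated times, 30 held and 0 turned. The counts of genes moved more, and the cause was not tested. Median prior degrees of freedom, 10.2 in the reported fit, were 20.4 and 19.4 without 2 h replicates 1 and 2. They were 15.7 with the GC and length trend removed. In these settings more genes were called against 0 h. Without either 0 h library they were 7.57, and fewer genes were called. Without a 6 or 20 h library they were 12.3 to 12.8, yet fewer genes were called as well. Without a low-count filter edgeR estimated infinite prior degrees of freedom, against a median of 10.2 with it, so the spread of single genes carried no weight in that setting. The numbers of genes higher and lower were as follows. With the settings reported above they were 99 and 48 at 2 h against 0 h, 133 and 31 at 6 h against 0 h, 402 and 191 at 20 h against 0 h. Between stimulated times, before any change of setting, they were 52 and 27 at 6 h against 2 h, 127 and 44 at 20 h against 6 h, 286 and 303 at 20 h against 2 h, with 625 genes over the 4 time points. With the GC and length trend removed they were 249 and 193 at 2 h against 0 h, 330 and 243 at 6 h against 0 h, 1232 and 784 at 20 h against 0 h. Between stimulated times, also without that trend, they were 169 and 88 at 6 h against 2 h, 506 and 292 at 20 h against 6 h, 699 and 472 at 20 h against 2 h, with 1946 genes over the 4 time points. With the library code series as a block they were 227 and 126 at 2 h against 0 h, 195 and 92 at 6 h against 0 h, 713 and 488 at 20 h against 0 h. Between stimulated times, also with the block, they were 115 and 73 at 6 h against 2 h, 261 and 138 at 20 h against 6 h, 670 and 863 at 20 h against 2 h, with 1549 genes over the 4 time points. Without a low-count filter they were 368 and 157 at 2 h against 0 h, 216 and 98 at 6 h against 0 h, 672 and 464 at 20 h against 0 h. Between stimulated times, also without the filter, they were 151 and 153 at 6 h against 2 h, 256 and 169 at 20 h against 6 h, 621 and 978 at 20 h against 2 h, with 1839 genes over the 4 time points. At an adjusted p under 0.01 they were 43 and 10 at 2 h against 0 h, 77 and 10 at 6 h against 0 h, 182 and 46 at 20 h against 0 h. Between stimulated times, also at that threshold, they were 19 and 7 at 6 h against 2 h, 42 and 16 at 20 h against 6 h, 95 and 74 at 20 h against 2 h, with 278 genes over the 4 time points. With DESeq2 they were 159 and 94 at 2 h against 0 h, 153 and 56 at 6 h against 0 h, 466 and 223 at 20 h against 0 h. Between stimulated times, also with DESeq2, they were 83 and 53 at 6 h against 2 h, 177 and 69 at 20 h against 6 h, 377 and 391 at 20 h against 2 h, with 945 genes over the 4 time points. With the 4 libraries compared alone they were 82 and 33 at 2 h against 0 h, 268 and 165 at 6 h against 0 h, 996 and 741 at 20 h against 0 h. Between stimulated times, also with 4 libraries, they were 9 and 2 at 6 h against 2 h, 374 and 255 at 20 h against 6 h, 131 and 85 at 20 h against 2 h. Leaving out 1 library gave the following ranges. Each highest count of genes came without 1 of the 2 h libraries. In the comparisons that involve 2 h this was replicate 2, so that the 2 h library left was replicate 1, the one with the strong GC trend. At 2 h against 0 h, 30 to 1430 genes were higher and 4 to 973 lower. At 6 h against 0 h, 41 to 269 genes were higher and 1 to 155 lower. At 20 h against 0 h, 55 to 976 genes were higher and 10 to 699 lower. At 6 h against 2 h, 16 to 974 genes were higher and 6 to 1196 lower. At 20 h against 6 h, 0 to 377 genes were higher and 5 to 274 lower. At 20 h against 2 h, 36 to 2146 genes were higher and 28 to 2222 lower. Over the 4 time points 191 to 4113 genes differed. Lists called at 2, 6 and 20 h numbered 11, 14 and 12, and 4, 6 and 4 with an estimated correlation. They numbered 7, 8 and 9 with fry, 12, 15 and 13 with the GC and length trend removed, and 8 to 15, 11 to 15 and 11 to 14 with 1 library left out. Without 2 h replicate 1 the immediate-early list at 2 h turned in direction (adjusted p = 0.626, against 1.04e-05 to 0.626 over the left-out libraries), and without 6 h replicate 2 the cell cycle list did at 6 h (adjusted p = 0.639, against 8.46e-09 to 0.639). The replicate number coincides with the library code series. Deviations from the group means correlated between the libraries of 1 code series at -0.076 to 0.19 over the 6 pairs of time points. These correlations do not exclude a pairing by series. With the series as a block the median prior degrees of freedom were 24.4, against 10.2 without it. The reported fit has no block because the labels do not say what a series marks. Scaling moved the median log2 fold change of all genes to between -0.014 and 0.0083. At this depth and with 2 libraries per group, changes near 0.5 on the log2 scale were often missed, with 59.7% recovered in the simulated comparison of 2 h with 0 h over 14148 genes.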

Other observations

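The tests of unequal depth and of low counts for the 2 h libraries, of the GC trend in each of these libraries, of interferon gene counts and of time in culture were chosen after the values they measure had been seen, and the bounds of the low-count and interferon gene tests were set anew after a first value.

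Other genes fell at 20 h. EPHB6, an ephrin receptor without kinase activity, fell by 0.94 on the log2 scale, PTK2B, a focal adhesion kinase relative, by 0.81 and OSR2, a transcription factor, by 0.81. DHRS3, which reduces retinal, fell by 0.65. These 4 calls were lost without 0 h replicate 1, and that of EPHB6 also without 20 h replicate 2. The transcription factor gene NFE2L3 rose with time, from 5.52 ± 0.19 CPM (SD, n = 2) at 0 h to 8.11 ± 0.39 at 6 h, with a log2 fold change of 1.12 ± 0.12 SE at 20 h. TRIM47, a ubiquitin ligase gene, rose from 4.62 ± 0.51 to 9.13 ± 1.5, 13.2 ± 2.7 and 12.2 ± 0.26 CPM. The calls of NFE2L3 at 6 h and of TRIM47 at 2 h were lost without either 0 h library, and that of NFE2L3 at 6 h also without either 6 h or 20 h library, with DESeq2, with limma-voom, with a stricter low-count filter and on the deposited log2 values (adjusted p of 0.0515 to 0.0737 in these 4). IL32 was at 3.10 ± 0.71 CPM at 0 h and at 8.13 ± 0.087 and 8.29 ± 0.17 CPM at 6 and 20 h.

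The 2 h libraries differed from each other more than the other pairs did, and no biological explanation was tested, since both carry the same label. A ratio of total counts of 1.36, in the 20 h pair, went with a smaller spread than in the 2 h pair, which argues against unequal depth. Over genes with a mean of at least 500 counts the spread of the 2 h pair was 1.73 times the largest of the other pairs, which argues against low counts. GC content and transcript length accounted for an R squared of 0.34 of the difference between the 2 h libraries, against 0.028 to 0.0722 in the other pairs. The SD was 0.321 over the 14289 genes tested, and 0.255 over the 13461 genes with GC values once that trend was removed. After the removal the other pairs had 0.232 to 0.24, so the 2 h pair still differed most. The trend was strongest in 2 h replicate 1 against the other time points (0.412, with 0.00855 in replicate 2 and at most 0.155 in the other libraries). A GC-dependent step in the preparation or sequencing of 2 h replicate 1 is therefore a candidate cause.

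Interferon-stimulated genes had a median log2 fold change of 0.428 at 20 h. A single library is argued against, since the median was 0.417 or more whichever of the 4 libraries was left out, and the trend with GC content and length is argued against by a median of 0.417 after its removal. Of the 21 type I and III interferon genes, IFNE held all 23 counts of the 6 h libraries (0.452 and 0.217 CPM of the unscaled library total, against 0.297 and 0.337 at 2 h and 0.235 and 0.222 at 0 h), and the other 20, IFNB1 among them, had 0 counts in each library of 0, 2 and 6 h, which at 6 h allows up to 0.0969 and 0.0724 such CPM of each. This gave no sign of their transcription at 0, 2 or 6 h. It leaves open levels below that floor and any time between 0 and 2 h, 2 and 6 h, or 6 and 20 h. Time in culture and the antibody cannot be told apart, because the number of unstimulated libraries kept for 20 h was 0.

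Cell cycle genes had a median log2 fold change of 0.551 at 20 h. Leaving out each of the 4 libraries gave medians of 0.471 or more, which argues against a single library, and removing the trend with GC content and length left 0.533, which argues against that trend. Time in culture and the antibody cannot be told apart here either, with 0 unstimulated libraries at 20 h. The rise may therefore come from the antibody or from growth during the extra 20 h after plating.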
